A study of Homo sapiens with 47 samples.

How the data were processed

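Cell-free RNA is the RNA found outside cells in body fluids, here in blood plasma. Per the labels' protocols, RNA was purified from human plasma with a kit for circulating and exosomal RNA, and polyadenylated RNA was taken into libraries by a low-input Nanopore ligation protocol read on a PromethION flow cell. The labels place the 47 libraries in 3 groups: 19 from people with esophageal adenocarcinoma, 12 from people with Barrett's esophagus, a columnar change of the esophageal lining that can precede adenocarcinoma, and 16 from controls. Per the series' design text, the long reads served to find transcripts, and the resulting models were added to existing gene and repeat annotation.

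The single file used here is that annotation of genes, transcripts and exons, which the authors deposited as 1 list pooled over the whole series. Its measured values are start and end coordinates and descriptive attributes, both of the kind "other": they are positions and names, not read counts. Per the file's source field, each line was written by IsoQuant, a program that assigns long reads to annotated genes and calls further transcript models; its version is not given in the sources used here. Per the submitters' processing notes the genome build was hg38. The aligner, the minimum read support of a model and the GENCODE release are not given in the sources used here.

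The file holds no value per library, and the number of columns of per-sample values is 0. Levels in adenocarcinoma, Barrett's esophagus and control plasma were therefore not analysed here, no library can be named in any result, and the depth per library is unknown. How many reads or libraries support a model is unknown too. No paired analysis was possible because no library has a value of its own. All p-values below compare entries of 1 annotation; genes and transcripts are not independent replicates, so these p-values describe the list and not the groups of people. Intervals on shares are 95% Wilson intervals and cover counting error only.

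Entries with Ensembl transcript identifiers were taken as the catalogue layer (GENCODE) and all other entries as discovered. Of the catalogue transcripts, 174947 also occur in GENCODE 29, and 174947 of these have identical exon coordinates there, so the reference annotation and the file share a build. Repeat entries and a genome sequence were not used here. The tests of repeat content, of repeats at transcript starts and ends, and of splice site dinucleotides that had been planned were not run.

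Each discovered transcript was given the first position class that applied: the same intron chain as a catalogue transcript, a shared splice junction, overlap by 1 base or more with a catalogue exon on the same strand, then with an exon on the other strand, then with a gene span (intron) on the same strand, then on the other strand, and otherwise intergenic. Spliced length and exon number were compared with catalogue transcripts of lncRNA genes and of protein-coding genes by a two-sided permutation test of the difference of medians with 100000 resamples, of which the smallest possible p is 1e-05. Densities by region used the midpoint of each single-exon entry on the autosomes and X, leaving out 1 Mb windows without any discovered entry. Chromosome Y was left out of named genes, of the counts by gene class and of the results by chromosome, but its protein-coding genes stayed among the 19841 genes of the gene list tests.

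There were 14 gene lists, fixed before the data were examined: red blood cells, platelets and megakaryocytes, neutrophils, monocytes, lymphocytes, liver, esophageal squamous epithelium, columnar and intestinal epithelium, esophageal adenocarcinoma drivers, fibroblasts and muscle, widely expressed genes, cytosolic ribosomal proteins, nuclear genes of oxidative phosphorylation, and mitochondrially encoded genes. All members of 13 lists matched a gene name in the file. The mitochondrial list, with 13 members, matched none, because the file has 0 entries on the mitochondrial chromosome. A gene counted as having a discovered transcript when 1 overlapped its exons on its strand or carried its identifier. Lists were tested against all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 13 lists, and against 10000 random lists of the same size matched on exonic length (10 strata) and number of catalogue transcripts (5 strata), for which the smallest possible two-sided p is 0.0002.

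Genes were named by a rule fixed at the same time: the 10 protein-coding and 10 lncRNA genes with the most discovered transcripts over their exons on the strand, the 4 members of each list with the most, and the 10 intergenic loci with the most transcripts, leaving out Y-linked genes and XIST. Some genes that the rule takes are not reported here. Other genes named were chosen after their values were seen, and the text says so.

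For transcript ends, GENCODE 29 transcript sequences stood in for the genome. An end was used when the 40 bases before it and the 20 bases after it lay within 1 reference exon, on either strand, which held for 4867 of 286777 entries on the autosomes and X. The share followed by 12 or more A in 20 bases, and the share preceded by a polyadenylation hexamer (AAUAAA or AUUAAA in RNA), were compared with random positions of the same exons in 10000 draws. Intron entries were also tested gene by gene for the share on the gene's strand, by an exact two-sided binomial test against the overall share for genes of that strand, for genes with 10 or more such entries, with Benjamini-Hochberg adjustment.

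The tests were first tested on simulated data. The share of intron entries on the gene's strand was simulated for 3894 genes with 200 changed. Of genes with a share raised to 0.85, 84 of 100 were recovered, and of those with a share lowered to 0.08, 56 of 100, with 5 false calls. For the list test on 19841 genes, 13 of 200 random lists had an unadjusted Fisher p under 0.05, as did 4 of 100 random lists by the matched test. A list of 30 genes that all had a discovered transcript gave a Fisher p of 3.42e-18. For the test of medians, a planted shift of 50 bases was returned as 48.

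The alternatives tried were main chromosomes only, overlapping entries merged into loci, entries of 200 bases or more, spliced entries only, the longest entry per gene, overlap of 50% of the exonic bases, protein-coding genes only, strand ignored, matched random lists and 6 A in a row. Added after seeing the data were, among others, spliced transcripts under the gene's own identifier and the blood lists without lymphocytes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9.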

Results

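Long reads of polyadenylated cell-free RNA from 47 human plasma samples were used to extend the human gene catalogue. The groups were esophageal adenocarcinoma (n = 19), Barrett's esophagus (n = 12) and controls (n = 16). The series asks which RNAs circulate in plasma in these conditions and whether they differ between the groups. The extended annotation pools all groups, so it shows where transcript models were added to the catalogue. It does not show how much plasma RNA came from catalogue transcripts. Which group the added models came from was not analysed here.

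Models added from plasma outnumbered the catalogue transcripts, and nearly all of them were short and unspliced. The catalogue layer held 241884 transcripts of 58606 genes, and the discovered layer 287644 transcripts, 54.3% of the 529528 transcripts in the annotation. Discovered exons covered 114 Mb, against 156 Mb for catalogue exons. Of the discovered transcripts, 287176 (99.8%) had 1 exon and 468 were spliced, whereas 10.1% of catalogue transcripts had 1 exon. Catalogue genes received only 298 of the discovered transcripts under their own identifiers, in 280 genes, and the other 287346 formed 286955 genes of their own. Of these genes, 286587 had 1 transcript each.

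Discovered transcripts were shorter than those of both catalogue gene classes. Their median length was 335 bases (interquartile range 238 to 492), against 952 bases (590 to 1594) for 51334 transcripts of lncRNA genes, which make RNA without a known protein product. Transcripts of protein-coding genes had a median of 1124 bases (594 to 2637; 164420 transcripts). The differences of -617 and -789 bases each had the smallest p that the permutation test could give, 1e-05. Median exon number was 1 in discovered transcripts, 3 in those of lncRNA genes and 5 in those of protein-coding genes (p = 1e-05 for each, two-sided permutation test). Among spliced entries, the discovered median of 432 bases was again below the 947 bases of lncRNA genes, while the median exon number was 3 in both. The longest discovered entry, a single exon of 91395 bases on chromosome 2 (218256504 to 218347898, plus strand, hg38), stood far from the 95th percentile of 841 bases.

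**Figure D1:**
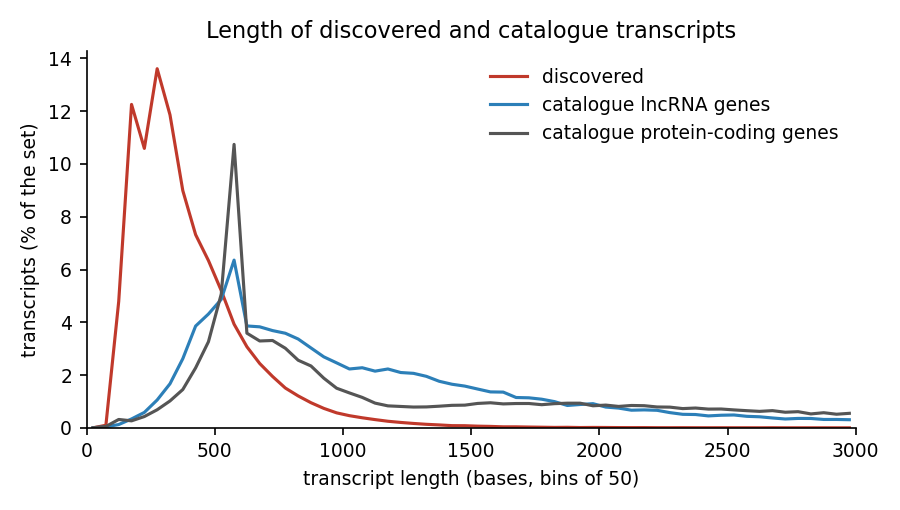
Length in bases (x axis, bins of 50 bases) against the percent of transcripts in each set (y axis) for discovered transcripts, catalogue lncRNA transcripts and catalogue transcripts of protein-coding genes. The discovered curve peaks below the medians of 952 and 1124 bases of the catalogue sets, with its own median at 335 bases.

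Introns and the regions between genes held most discovered transcripts, and catalogue exons few. Introns on the same strand as the gene held 75403 (26.2%, 95% interval 26.1 to 26.4) and introns of genes on the other strand 93723 (32.6%, 32.4 to 32.8). Intergenic sequence held 101574 (35.3%, 35.1 to 35.5), including 416 on sequences where the file has no catalogue gene. An exon was overlapped on the same strand by 9664 (3.36%) and on the other strand by 7028 (2.44%), 252 shared a splice junction with a catalogue transcript and 0 had the intron chain of one by coordinates, although the file's own notes record a full splice match for 3. With only protein-coding genes counted, the intergenic share was 49.4%; with an overlap of 50% of the exonic bases required, the share over exons of the other strand was 0.422%.

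Per megabase, single-exon entries were densest in introns and sparsest in exons. There were 111 per Mb in introns (Poisson 95% interval 110 to 111) and 91.2 per Mb between genes (90.7 to 91.8). Exons had 52.7 per Mb (51.5 to 53.9). Introns and exons were thus at 1.21 and 0.577 times the intergenic density. Models that match a catalogue transcript are not counted as discovered, so a low density in exons can follow from the definition. These densities do not give the share of plasma RNA from each region. Where genes were annotated on 1 strand only, 64608 of 158331 intron entries lay on the gene's strand, 40.8% (40.6 to 41.0). Over exons the order was the other way, with 7495 of 13629 entries on the gene's strand, 54.99% (54.2 to 55.8). The minus strand carried 52.4% of all discovered entries (52.3 to 52.6), and between genes 52.2% (51.9 to 52.6), against 49.3% of catalogue genes. Of spliced entries, 183 of 468 lay on the minus strand, 39.1% (34.8 to 43.6): 141 of the 298 in catalogue genes, but 42 of the 170 in discovered genes, of which 123 lay off the main chromosomes.

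Some of the single-exon entries carry a note on the closest catalogue transcript. Of these 15345 entries, 8525 are recorded as running into an intron of it, 8664 as ending at another polyadenylation site and 406 as holding an unspliced intron, and an entry can fall under several of these. Among protein-coding genes, 5202 of 19795 (26.3%) had at least 1 discovered transcript over their exons on the strand, and 3873 had exactly 1. Among lncRNA genes, 1722 of 17162 (10.03%) had at least 1. Related to exon length the classes were close, at 0.643 entries per 10 kb of exon for protein-coding and 0.591 for lncRNA genes.

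The protein-coding genes with the most discovered transcripts over their exons had 5 to 7 each. FOXP1, a transcription factor gene on chromosome 3 (70954693 to 71583978), TAOK3, a protein kinase gene on chromosome 12, and TTN, which encodes the giant muscle protein titin on chromosome 2, had 7 each. STRN, RNF115, ANKRD12, TCF4 and ITGA11, an integrin gene, had 6 each. TRIM44 and LYN, which encodes a Src family kinase of blood cells, had 5 each. Against exon length these counts ranged from 0.588 per 10 kb in TTN, below the protein-coding value, to 8.11 per 10 kb in LYN (chromosome 8, 55879835 to 56014169). None of the 10 genes held a spliced discovered transcript under its own identifier.

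Among lncRNA genes, XACT on the X chromosome (113616300 to 114059289) had 19 discovered transcripts over its 347964 exonic bases. KCNQ1OT1, the imprinted antisense RNA of the KCNQ1 locus on chromosome 11, had 8 over 91667 bases, and BASP1-AS1 and TSIX had 5 each. MALAT1, an abundant nuclear RNA encoded on chromosome 11 (65497688 to 65506516), GABPB1-AS1, ENSG00000279159, ENSG00000286125 and ENSG00000259370 had 4 each. Per 10 kb of exon, XACT had 0.546 and KCNQ1OT1 0.873, close to the lncRNA value, while MALAT1 had 4.53.

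Spliced discovered transcripts lay more often in genes of lymphocytes and of the ribosome than in other genes. In the lymphocyte list, 5 of 26 genes had a spliced discovered transcript (19.2%, 95% interval 8.51 to 37.9), against 1.32% of other protein-coding genes (odds ratio 17.8, Fisher's exact test, adjusted p = 0.000288). They were GNLY, which encodes the cytotoxic granule protein granulysin, with 2, and LCK, CD8B, CCR7 and CD3D, which encode a kinase, a coreceptor, a chemokine receptor and a receptor chain of T cells, with 1 each. Of the cytosolic ribosomal protein genes 7 of 77 had one (9.09%, odds ratio 7.50, adjusted p = 0.000517), among them RPS15 with 2 and RPS14, RPS2, RPL41, RPL31 and RPL35 with 1 each. Of the platelet and megakaryocyte genes 3 of 31 had one (9.68%, odds ratio 7.93, adjusted p = 0.0355): ITGA2B, the integrin chain of the platelet fibrinogen receptor, PTCRA, which encodes the pre-T cell receptor chain, and GP1BB. These members were named after their values were seen.

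Against random lists matched on exonic length and number of catalogue transcripts, adjusted p over 10000 lists was 0.0026 for lymphocytes, 0.0143 for ribosomal proteins and 0.0407 for platelets. The platelet value depends on GP1BB, whose spliced transcript does not carry the identifier of GP1BB. Counting only transcripts under a gene's own identifier, a choice made after seeing the data, platelets had 2 of 31 (adjusted p = 0.159, and 0.367 against matched lists). Lymphocytes kept 5 of 26 (0.00021, and 0.0026) and ribosomal proteins 7 of 77 (0.000342, and 0.0091). Red blood cell genes had 2 of 32 (EPB41 and BNIP3L; odds ratio 4.92, adjusted p = 0.179), and neutrophil genes 1 of 25 (LCN2), values that did not pass the test. Adenocarcinoma driver genes had 2 of 30, CCND3 and PIK3CA (adjusted p = 0.179), and widely expressed genes 1 of 26, ACTG1, with 2 transcripts. On the main chromosomes none was found in the 18 monocyte, 28 liver, 26 squamous epithelium, 31 columnar epithelium, 19 fibroblast and muscle and 39 oxidative phosphorylation genes. With lists of this size, 0 of 28 liver genes still allows a share of up to 12.1% (Wilson upper bound), so spliced transcripts of these tissues cannot be excluded.

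**Figure D2:**
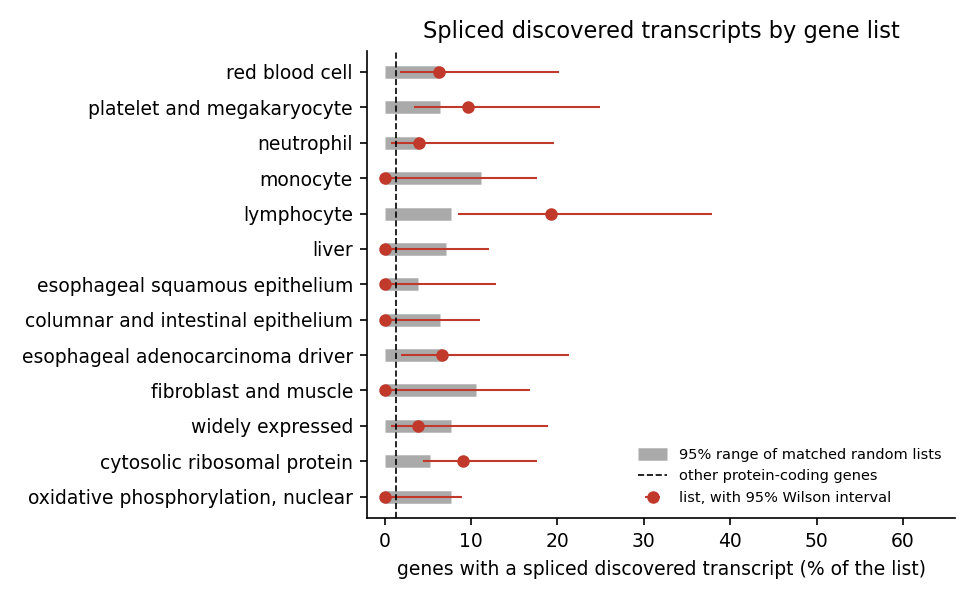
Percent of each gene list with a spliced discovered transcript (x axis, red points with 95% Wilson intervals), beside the 95% range of 10000 matched random lists (grey bars) and the share among other protein-coding genes (dashed line). Lymphocyte genes, at 19.2%, lie above the range of their random lists, as do ribosomal protein genes at 9.09% and platelet genes at 9.68%, the last only while GP1BB is counted.

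With unspliced entries included, no single list passed the adjusted test at an overlap of 1 base. Adenocarcinoma driver genes had the highest share, 15 of 30 (odds ratio 2.82, p = 0.00575, adjusted p = 0.0748), among them SMAD2 with 4, APC with 3 and ERBB3 with 2, and 15 members had none. These genes are long, and matched random lists had a median of 13 genes with an entry (adjusted p = 0.872). With an overlap of 50% of the exonic bases required, 12 of 30 driver genes had one (adjusted p = 0.029), but not against matched lists (adjusted p = 0.698). Lymphocyte genes had 11 of 26 (GNLY and KLRD1 with 2, IL7R and LCK with 1; 15 without; adjusted p = 0.24, and 0.0676 against matched lists). At 50% overlap they had 8 of 26, which passed against matched lists (adjusted p = 0.0442) but not against all other genes (0.239).

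The 5 blood cell lists pooled had an entry in 38 of 132 genes (28.8%, Fisher p = 0.488), more than the median of 25 in matched lists (p = 0.0066). At 50% overlap they had 32, against a matched median of 15 (p = 0.0002, the smallest possible). Pooling was not part of the planned list test, and the p-values of the pooled set are not adjusted. Singly, the other 4 blood lists did not pass the Fisher test at 1 base, with adjusted p of 0.711 for red blood cells, 0.607 for platelets, 1 for neutrophils and 0.24 for monocytes. In red blood cells 10 of 32 genes had an entry, with EPB41 at 3, SLC4A1, which encodes a major membrane protein of the red cell, at 2 and ANK1 at 1, and 22 had none. In platelets and megakaryocytes 10 of 31 had one, with ITGA2B at 4, ITGB3 at 3, THBS1 at 2 and TUBB1 at 1, and 21 had none. In neutrophils 6 of 25 had one, with CXCR2 and NAMPT at 3 and CXCR1 and LCN2 at 1, and 19 had none. In monocytes 1 of 18 had one, and 17, among them AIF1, CD14 and CD163, had 0 on the main chromosomes.

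Lists of epithelium, liver and connective tissue showed no difference that passed the adjusted test. Esophageal squamous genes had 2 of 26 (7.69%, odds ratio 0.234, p = 0.0412, adjusted p = 0.24), TP63 and SOX2 with 1 each, and 24, among them CNFN and CRNN, had none. Columnar and intestinal genes had 5 of 31 (adjusted p = 0.492), with CLDN18 and ANPEP at 2 and VIL1 and CLDN3 at 1, and 26 had none. Liver genes had 5 of 28 (adjusted p = 0.607), with CPS1 at 2 and TF, CRP and ALB at 1, and 23 had none. Fibroblast and muscle genes had 8 of 19 (adjusted p = 0.317), with DCN at 2 and COL6A3, COL1A2 and FAP at 1, and 11 had none.

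The lists of genes used by most cells did not differ from other genes by this test. Ribosomal protein genes had 16 of 77, with RPS14 at 3 and RPL14, RPS15 and RPL37A at 2, and 61 had none. Nuclear genes of oxidative phosphorylation had 9 of 39, with ATP5MC1, COX5B, NDUFB1 and ATP5MG at 1, and 30 had none. Widely expressed genes had 8 of 26, with ACTG1 at 2 and NACA, HSPA8 and TUBA1B at 1, and 18 had none. The adjusted p of these lists lay between 0.561 and 0.927.

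The spliced transcripts of catalogue genes used mostly known introns. Of the 562 introns in these 298 transcripts, 464 (82.6%) were catalogue introns, and in 208 transcripts all introns were. This holds only for transcripts under a catalogue gene. How the caller assigns spliced models to genes is not given in the sources used here. If shared introns decide it, the share of known introns follows in part from that assignment. The 170 spliced transcripts of discovered genes had 457 introns, of which 0 were catalogue introns, but 123 of these transcripts lay where the catalogue layer has no transcript. Of the 280 host genes, 250 were protein-coding and 22 lncRNA genes. ACRBP on chromosome 12 (6638075 to 6647433) and RBX1 on chromosome 22 (40951325 to 40973309), a subunit gene of cullin ubiquitin ligases, had 3 each. A further 14 genes had 2 each, among them GNLY, HEMGN, which encodes the blood progenitor protein hemogen, IFI16, MEF2C and RPS15. The remaining 264 hosts had 1. These hosts were named after their values were seen.

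The ends of discovered entries were compared with sequence where they fell inside reference exons. Of 4867 such ends, 27.1% (25.8 to 28.3) had a polyadenylation hexamer in the 40 bases before the end, 5.07 times the 5.33% at random positions of the same exons (p = 0.0002, the smallest the draws could give, two-sided). In exons on the same strand, hexamers were most frequent 21 to 25 bases before the end, at 10.7 per 100 ends, and in exons on the other strand that bin held 1.75 per 100 and the highest bin, at 11 to 15 bases, 4.44. Ends in exons on the other strand had a hexamer in 13.8%, 2.23 times the random 6.20% (p = 0.0002). For A after the end, 2 measures went in opposite directions: 6.49% of ends (5.83 to 7.22) had 12 or more A in the next 20 bases, 1.81 times the random 3.58%, while 6 A in a row followed 2.42% of ends, 0.718 times the random 3.37% (p = 0.0002). These ends are 1.7% of the entries on the autosomes and X, and ends in introns and between genes were not analysed here.

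**Figure D3:**
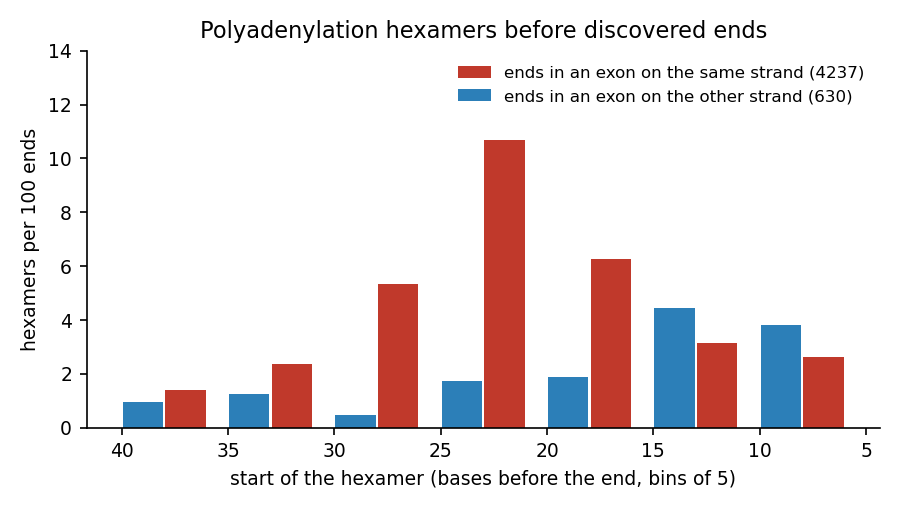
Polyadenylation hexamers per 100 discovered ends (y axis) by distance of the hexamer start before the end in bases (x axis, bins of 5), for ends inside a reference exon on the same strand (red) and on the other strand (blue). On the same strand the highest bar is 10.7 per 100 ends at 21 to 25 bases.

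Autosomes carried discovered transcripts at similar densities. The mean over 22 autosomes was 95.9 ± 12.5 per Mb (SD, n = 22 autosomes), with a range from 68.8 on chromosome 21 to 128 on chromosome 19, the chromosome with the highest gene density at 51.2 genes per Mb. Chromosome X had 54.7 per Mb, below every autosome, with 14.5 genes per Mb. Across 23 chromosomes the density went with catalogue gene density (Pearson r = 0.555, permutation p = 0.0111, adjusted 0.0138; Spearman rho = 0.465, permutation p = 0.0256, adjusted 0.0381; 4 relations computed). Without chromosomes 17 and 19, the 2 farthest from the median gene density, r was 0.174, so the relation rests on those chromosomes. Both densities were taken per Mb up to the last annotated base of each chromosome. Windows without a discovered entry, 171 of 3043 windows of 1 Mb, were kept here. They lower the density of chromosomes that hold many of them, and how far this shapes the range was not tested.

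**Figure D4:**
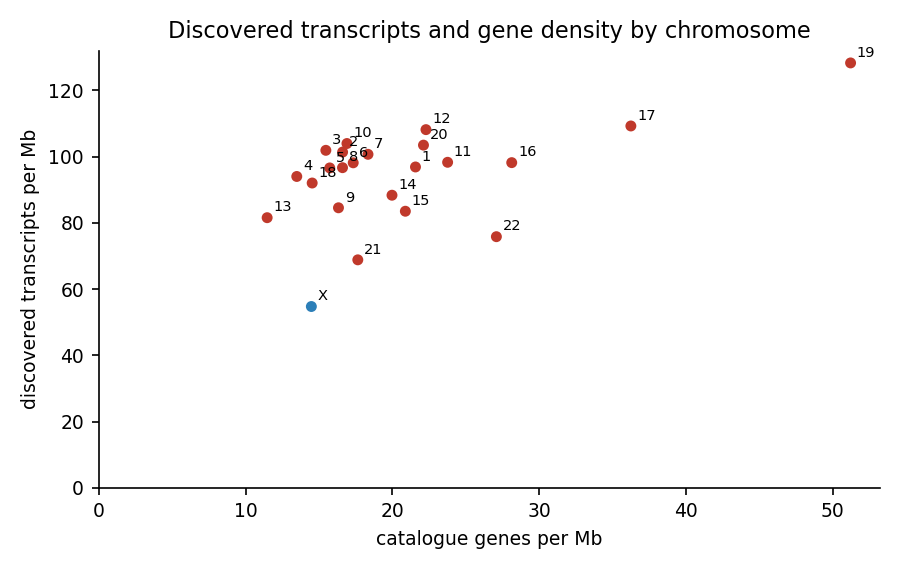
Discovered transcripts per Mb (y axis) against catalogue genes per Mb (x axis), 1 point for each autosome (red) and for X (blue), with the chromosome written beside it. Most autosomes lie near the mean of 95.9 per Mb, chromosome 19 is highest at 128 and X lowest at 54.7.

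The 101574 entries outside catalogue genes formed 99673 loci strand by strand, and only 1534 loci held more than 1 transcript. The locus with the most, 12 transcripts, all spliced, lay on the plus strand of an unplaced sequence (2268 to 85030). An unlocalized sequence of chromosome 17 followed with 8 (25334 to 213233), and a region of chromosome 5 (49656349 to 49667431, plus strand) had 7, all spliced. Loci on chromosome 3 (103673557 to 103709944) and on 2 other sequences of chromosome 17 had 4 each. Loci of 3 transcripts lay on chromosome 2 (17822912 to 17824969), chromosome 9 (33091432 to 33093290), chromosome 20 (16878207 to 16879844) and another unplaced sequence. Of these 10 loci, 5 lie on sequences without any catalogue gene in the file, where no overlap with a gene could be seen.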

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

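All tests in this part were chosen after the entries had been seen. Outside the main chromosomes, on alternate haplotype, unplaced and unlocalized sequences, the catalogue layer had 0 transcripts, so the 416 discovered entries found there were counted as intergenic above and entered no comparison by gene or gene list. They were spliced far more often than entries elsewhere, 123 of 416 (29.6%) against 345 of 287228 (0.12%) on the main chromosomes. On alternate haplotype sequences, which are second versions of variable regions of the genome, 93 of 184 entries were spliced.

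Most of the spliced entries on alternate haplotypes had the structure of a gene that the catalogue places on the main chromosome. Of 89 with 3 or more exons, 85 had the same internal exon lengths, and intron lengths within 5%, as a catalogue transcript of the same chromosome, and 16 matched one on another chromosome. With introns within 1%, the numbers were 82 and 2. The matches with the most transcripts were AIF1, a macrophage and monocyte gene, with 11, LST1, a leukocyte gene, with 9, NDUFA3 of respiratory complex I with 9 and RPS9 with 6. CLIC1, PSMB9, RPS18 and SMDT1 had 4 each. These counts add matches over all alternate haplotype sequences, of which 75 held discovered entries. If several sequences carry the same gene, 1 transcript structure can be counted more than once, which was not separated. In all, 36 protein-coding genes were matched, 16 of them on chromosome 6, including the antigen presentation genes HLA-C, HLA-DRA, HLA-DPA1 and HLA-DPB1. AIF1 and LST1 belong to the monocyte list and had 0 discovered transcripts on the main chromosome, LTB (1 match) belongs to the lymphocyte list, and RPS9 and RPS18 to the ribosomal list, so the counts by gene list above leave out these copies.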

How the results depend on the processing

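The alternatives were planned before the data were examined, except 5: the window filter, the restriction of intron entries to protein-coding genes, the match of intron lengths, spliced transcripts under the gene's own identifier, and the blood lists without lymphocytes. The end sequences, too, were tested in a form chosen after seeing the data. Lengths kept their direction and p under all 3 alternatives run. Among spliced transcripts the exon number difference from lncRNA genes was 0 (p = 1). The number of discovered transcripts was 287228 on main chromosomes and 282481 as merged loci.

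With an overlap of 50% of the exonic bases, the shares in the position classes became 1.87% and 0.422% for exons on the same and other strand, 27.7% and 34.3% for introns, and 35.6% between genes. With protein-coding genes only they became 2.30%, 1.87%, 19.2%, 27.1% and 49.4%, which follows in part from the definition, since fewer bases then count as gene. The share of intron entries on the gene's strand was then 40.2%. The ratio of intron to intergenic density was 1.37 with all windows kept.

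The number of lists past an adjusted p of 0.05 was 0 by Fisher's exact test, 0 against matched random lists, 1 at 50% overlap (adenocarcinoma drivers) 3 among spliced transcripts and 2 among spliced transcripts under the gene's own identifier. Against matched lists at 50% overlap, lymphocytes passed (adjusted p = 0.0442). Of 52 list values under alternatives, 38 kept direction and call, 4 passed the test only there, and 10 changed direction. Of these 10, the ribosomal protein list passed the test among spliced transcripts (odds ratio 7.50, and 8.03 by own identifier), and its ratio was 1.19 at 50% overlap. The others passed no test: neutrophils 1.5 against matched lists, 1.23 at 50% overlap, 3.06 when spliced and 3.27 by own identifier, fibroblasts and muscle 0 in both spliced counts, oxidative phosphorylation 1.29 against matched lists. The platelet odds ratio was 7.93 when spliced and 5.44 by own identifier, where it passed no test. Enrichment of A after the ends became a depletion when counted as 6 A in a row (0.718 times random), and was 1.42 times (p = 0.142) for spliced entries; the cause was not tested. Planned tests of repeats, splice site dinucleotides and genome-wide A content were not run. Depth limits every statement of absence, since read support is unknown.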

Other observations

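The tests in the first paragraph were chosen after the entries had been seen. In the other paragraphs the main tests were fixed before their results were seen, but for patterns already noticed in these data. Counting hosts by the gene's own identifier was itself a choice made after seeing the data. The equal weighting of plus-strand and minus-strand genes and the count without lymphocytes were added after. Some genes passed a test for departure from the overall strand split of intron entries. Of 3894 protein-coding genes with 10 or more intron entries, 9 had an excess on the gene's strand (exact binomial test, adjusted p under 0.05). None had an excess on the other strand, and 425 had an unadjusted p under 0.05. The test takes the entries of a gene as independent and the share as common to all genes of a strand. Those 425 genes are more than the 0.05 share of all tested that this would give at most. Either many genes differ somewhat or the entries of a gene are not independent, and these were not told apart. If entries are not independent, the p-values are too small, so the 9 genes are not secure. In simulation it recovered 84 raised and 56 lowered shares of equal numbers planted, so it finds an excess on the other strand less often. KLHL20, a substrate adaptor gene of a cullin ubiquitin ligase on chromosome 1 (173714941 to 173786692), had 16 of 17 intron entries on its strand, against 37.5% over plus-strand genes (adjusted p = 0.00656). RYR3, a calcium release channel gene on chromosome 15, had 36 of 54 (adjusted p = 0.0312). ANTXR1 with 16 of 19, DNAH3 with 24 of 31, NIPAL2 with 13 of 14 and GALM with 15 of 18 followed (adjusted p = 0.0497 each). Of the genes in the 5 blood cell lists 10 could be tested, and 0 had such an excess. Within 1000 bases before gene starts, 674 of the intergenic entries lay on the gene's strand and 912 on the other (42.5%, 40.1 to 44.9), whereas at 10001 to 50000 bases the share was 50.4%. Within 1000 bases after gene ends it was 46.7% (44.5 to 48.95), but 50.03% at 1001 to 5000 bases, 50.8% at 5001 to 10000 and 48.4% at 10001 to 50000.

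Unspliced entries at a similar density in introns, between genes and on every autosome are what fragments of genomic DNA would give. The density ratio of introns to intergenic sequence, 1.21, lies in the range set for that explanation. No range was set for exons, which were at 0.577 times, a value that can follow from the definition of discovered entries. Nor was one set for autosomes, which ran from 68.8 to 128 discovered entries per Mb. In introns, a strand share of 40.8% on the gene's strand lies outside both ranges set for genomic DNA. For entries in introns and between genes that explanation stays open. No strand range was set for exons. With an overlap of 50% of the exonic bases, 5381 entries lay over exons of the same strand and 1215 over those of the other. These counts argue against genomic DNA as the main source of those exon entries, which are 1.87% and 0.422% of all discovered entries. For unspliced RNA of blood cells as the main source of intron entries, the value lay in the range set against it. Intron entries on the gene's strand were at 38.0 per Mb in the 5 blood cell lists, 0.927 times the median of matched lists (95% range 32.6 to 50.1 per Mb). This cannot decide the question, because random lists were not matched on expression and can hold genes of blood cells too. Red blood cell and platelet genes gave 60 and 45 of the 167 entries. Singly, neutrophil genes were at 1.27 times matched lists (17 entries), monocyte genes at 0.791 (9 entries) and lymphocyte genes at 0.881 (36 entries). How the caller treats same-strand reads in introns is not given in the sources used here. If it assigns them to known genes, it lowers both the density on the gene's strand and the strand share, so the pooled value does not exclude such RNA in the reads. Entries on the other strand in the 5 blood cell lists were at 0.931 times matched lists, so the pooled blood lists showed no shift between strands in introns. Over exons, 38 of 132 blood genes had an entry against a matched median of 25 (unadjusted p = 0.0066, matched random lists). At 50% overlap it was 32 against 15 (unadjusted p = 0.0002). Against all other genes the first count did not differ (28.8% against 26.2%, Fisher p = 0.488). These counts include spliced entries, which 11 of the 132 genes had (matched median 2). Entries over exons do not tell unspliced from spliced RNA, so for exon entries, too, the explanation stays open. Priming on internal runs of A could not be decided, since A-rich sequence followed single-exon ends at 1.84 times the random share, between the bounds set. In contrast, 6 A in a row followed them at 0.708 times. A polyadenylation hexamer preceded 26.7% of these ends, against 5.28% at random positions (5.06 times), a measure for which no bound had been set. Only the part of ends with sequence was tested. No explanation from the groups of people was tested, because the groups have no values of their own, and the orientation of repeats within introns was not analysed here.

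An excess on the minus strand because entries share the strand of their host genes is argued against, since in introns of plus-strand genes the minus share was 61.3%. In introns of minus-strand genes it was 43.1%, so intron entries lay mostly opposite to their hosts on both strands, which restates the share of 40.8%. With both kinds of gene given equal weight the minus share was 52.2%. A strand preference of sequencing, alignment or transcript calling remains a candidate explanation, as the minus share was 52.2% between genes, where entries have no host. Spliced entries did not share the excess, with 141 of 298 on the minus strand in catalogue genes and 42 of 170 in discovered genes, the latter mostly off the main chromosomes. Its source was not separated further, and no biological explanation was tested.

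Blood cell genes among the hosts of spliced transcripts are not accounted for by long exons or by many catalogue transcripts. Of 132 genes in the 5 blood cell lists, 10 were hosts, and of 10000 matched random lists the share with as many was 0, with 9 hosts in the highest. Lymphocyte genes gave 5 of the 10. Without that list, 5 of 106 were hosts (4.72%), against a median of 1 in matched lists (p = 0.0214). No other blood list passed alone against matched lists: adjusted p was 0.491 for red blood cells, 0.367 for platelets and 0.817 for neutrophils, and monocytes had 0 hosts on the main chromosomes. The pooled excess was thus still present without lymphocytes. A candidate explanation is that spliced models arise where transcripts are abundant in plasma, blood cells being one source. Abundance was not measured here, so this was not tested. Ribosomal protein genes, which all cells use, had a similar excess, with 7 hosts of 77. For other genes of most cells the lists were too small to show or exclude an excess. Oxidative phosphorylation had 0 hosts of 39 (Wilson upper bound 8.97%). Widely expressed genes had 1 of 26 (odds ratio 3.14, Fisher's exact test, adjusted p = 0.522). In the blood lists 94 of 132 genes had no discovered transcript over their exons. Among them were HBA1, HBA2, HBB, PF4, PPBP and S100A8, named after their values were seen. Transcripts that match the catalogue are not counted as discovered, so such a 0 does not show low abundance.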
